A study of Homo sapiens with 137 samples.

How the data were processed

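Gene expression was measured on human oligonucleotide arrays in 137 samples of plasma cells that had been selected from bone marrow with an antibody to CD138. Every sample carried the same label, which named lytic bone lesions seen by magnetic resonance imaging, so the samples formed 1 group and no group could be compared with another. Samples without lesions were not analysed here. The labels do not say that the samples come from separate patients, so each p-value measures the spread between samples.

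The values used were the deposited linear signal intensity of 12625 probe sets per array. The authors had scaled the arrays: the mean of each array, with the lowest and highest 2 percent of probe sets left out, lay between 1500.5 and 1500.9 in all 137 samples. The array software, its version and the summary method are not given in the sources used here. The signals ran from 0.0 to 179219.3, and array medians ran from 399.9 to 645.1. No pair of arrays was identical, and the median Spearman correlation of 2 arrays was 0.875.

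Of the 12625 probe sets, 10961 named 1 gene symbol in the annotation table, 545 named several and 1119 named none. The Entrez identifiers of 10949 probe sets were found in the RefSeq table of assembly GRCh38.p14, which was used for chromosome numbers alone. Probe sets for several genes or none, the 67 control probe sets and the genes of the Y chromosome, XIST and TSIX were left out of every gene-level step. Signals under 46.7, the median over arrays of the 10th percentile, were raised to that floor, which changed 9.81 percent of values, and were then put on the log2 scale, where the floor is 5.55. Each gene was represented by the probe set with the highest mean, which gave 8210 genes. A gene was kept when at least 10 percent of samples lay above 494.9, the median of all values, which left 5880 genes, and 5879 were tested against each of DKK1 and FRZB. DKK1, FRZB and the single genes tested from the lists of Wnt antagonists and osteoclast-activating factors were exempt from that filter.

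Relations across samples were fitted with limma (lmFit and eBayes), with the log2 level of DKK1 or of FRZB as a continuous covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. A slope is the change in a gene's log2 signal per log2 unit of DKK1 or FRZB. The two-sided tests of list scores and single genes used Pearson's r and Spearman's rho with 100000 permutations, whose smallest possible p is 1e-05. A list's score was the mean over its members of log2 values scaled to an SD of 1, with the gene it was tested against left out. The coherence of a list was the median pairwise Pearson's r of its members across samples, set against 10000 random lists of the same size and matched mean level.

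The 24 gene lists covered Wnt antagonists, Wnt ligands with receptors and pathway genes, osteoclast-activating factors, osteoblast and stromal markers, plasma cell markers, markers of B cells, T and NK cells, monocytes, granulocytes, erythroid cells and megakaryocytes, proliferation, the unfolded protein response, NF-kB targets, interferon-stimulated genes, MHC class II, ribosomal proteins, oxidative phosphorylation, the proteasome, glycolysis and hypoxia, the immediate early response, immunoglobulin genes, myeloma translocation and cyclin D genes, and cancer-testis antigens.

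Separate clusters of samples were called for a gene when a mixture of 2 normal components with a common variance had a BIC lower by over 10 than 1 component, means over 3 SD apart and at least 6 samples in each component. Where a measure fell into clusters, no pooled r is given, and r is given within the upper and lower components. Pooled limma slopes were the planned test and are given all the same, although DKK1, FRZB and some of the genes tested fell into clusters. Such a slope may rest on the difference between clusters. The number in the sample titles was the only possible batch the labels offered. Relations were recomputed within the 68 samples with the lower title numbers and the 69 with the higher title numbers.

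Named genes followed a rule. For DKK1 these were the 12 genes with the largest positive slope and the 12 with the largest negative slope among genes past the threshold whose slope had the same sign in both title-number subsets. For FRZB they were the 8 and 8 chosen in the same way, of which 1, with a larger negative slope than any that is named, is not reported here, and variable genes were the 20 with the largest SD. Members of the lists of Wnt antagonists, osteoclast-activating factors and translocation and cyclin D genes could be named whatever their test, and up to 4 members of any other list with the smallest p. Named outside that rule were SDC1, CD38, the level of JCHAIN, the split of IGKC and the ribosomal protein genes low on a few arrays. These should be read as chosen after their values were seen.

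The lists, the tests, the naming rule, the mixture rule and most alternatives were chosen before the data were examined. Those alternatives were a floor at the 25th percentile, a pseudocount, quantile normalization, no filter and a stricter filter, the mean of all probe sets of a gene, covariates for RNA quality, other cell types, proliferation and the translocation and cyclin D genes, leaving out the 2 samples farthest from the median or the 7 arrays with low median correlation, the title-number subsets and block, and a Spearman test per gene. RNA quality was the log2 ratio of the 3-prime to the 5-prime probe sets of GAPDH and ACTB, whose medians were -0.04 and 0.51. The remaining alternatives were chosen after seeing the data and are named in the closing section. There the genes related to DKK1 and FRZB under each alternative are given as a percent of the genes tested, and the rule of 1.5 times was applied to the counts. With the odd-numbered chromosome score as a covariate the counts were 58 and 127 of 5879 genes.

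The steps were tested on simulated or shuffled data. For limma the measured values of 5879 genes were kept and the level of DKK1 or FRZB was shuffled over samples. In each of 20 draws, 50 genes per correlation were given a known slope on the shuffled level. For DKK1 limma recovered 17.9 percent of the genes given a correlation of 0.2, 64.1 percent at 0.3, 96.5 percent at 0.4 and 100 percent at 0.5. For FRZB the shares were 18.2, 63.6, 98.1 and 100 percent. False calls, counted among the genes given no slope, had a median per draw of 6 for DKK1 and 5.5 for FRZB, with highest values of 44 and 27. The permutation test called 4.9 percent of unrelated scores at p under 0.05 and 99.1 percent of scores with a correlation of 0.35. The coherence step put 4.9 percent of unrelated lists and 100 percent of lists with a common factor above the 95th percentile. The mixture rule called 99.7 percent of samples drawn from 2 components 4 SD apart, 0.9 percent at 2 SD apart and 0.1 percent of single normal components. It also called 1.8 percent of single components with the skewness of DKK1 and 8.2 percent of those with the skewness of FRZB. The number of arrays limits the precision of every value. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.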

Results

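The data were array signals of plasma cells from bone marrow samples, all from the group labelled with lytic bone lesions on magnetic resonance imaging. The labels state that over 90 percent of the selected cells were plasma cells. The plasma cell surface genes SDC1, which encodes CD138, and CD38 had mean log2 signals of 15.23 ± 0.52 (SD over all samples) and 12.65 ± 0.80 (SD over all samples). JCHAIN, which encodes the joining chain of secreted immunoglobulin, reached 15.01 ± 0.85, and the plasma cell transcription factor gene IRF4 reached 14.18 ± 0.63. The keywords of the labels name DKK1, Wnt signaling and osteolytic lesions, so the question addressed was which genes moved with DKK1, and with FRZB, across the samples.

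DKK1 and FRZB encode secreted proteins that block Wnt signaling, a pathway that bone-forming cells need. DKK1 had a mean log2 signal of 10.41 ± 2.32 (SD over all samples) and a median signal of 1981. Its 90th percentile was 70.7-fold above its 10th percentile, and 10 samples lay at the floor. FRZB had a mean log2 signal of 11.21 ± 2.64 (SD over all samples) and a median signal of 3732. Its spread from the 10th to the 90th percentile was 139.5-fold, and 8 samples lay at the floor. By the mixture rule the levels of both genes fell into 2 clusters. The lower component of DKK1 held 29 samples and the upper the rest, with means of 6.92 and 11.42 that were 3.32 SD apart. The lower component of FRZB held 35 samples and the upper the rest, with means of 7.29 and 12.55 that were 4.03 SD apart. Simulated single skewed distributions passed the same rule in 1.8 percent of draws for the shape of DKK1 and in 8.2 percent for that of FRZB.

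**Figure D1:**
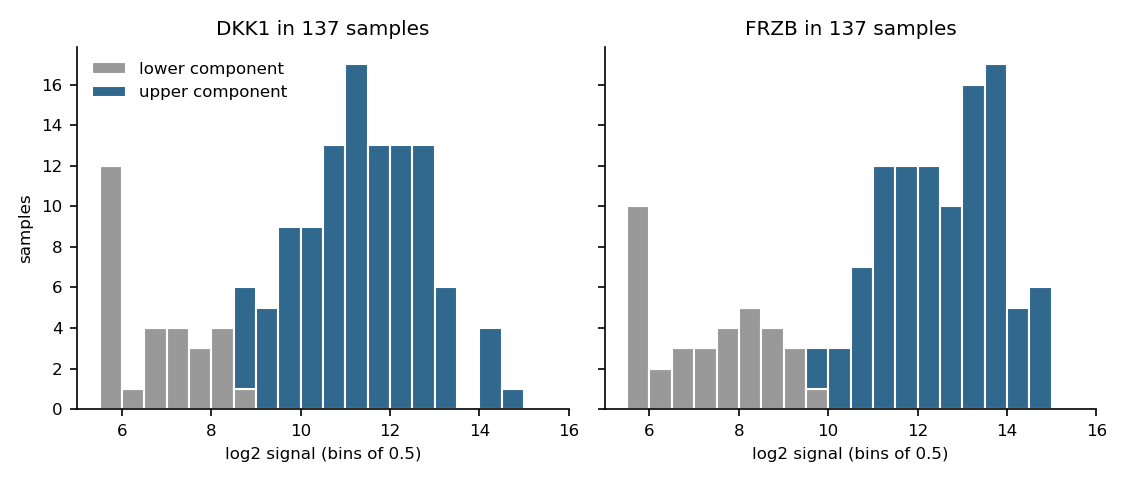
Number of samples (vertical axis) by log2 signal in bins of 0.5 (horizontal axis) for DKK1 and FRZB in all samples, coloured by mixture component. The lower components held 29 samples for DKK1 and 35 for FRZB.

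By the mixture rule several oncogenes that myeloma translocations can activate fell into 2 components. Translocations themselves were not measured, so an upper component does not mark one. FGFR3, a growth factor receptor gene, and NSD2, a histone methyltransferase gene, are both activated by the translocation between chromosomes 4 and 14. FGFR3 was high in 13 samples, with component means at least 300.6-fold apart since 24 samples lay at the floor, and NSD2 was high in 16 samples, with an 11.9-fold difference. CCND1, the cyclin D1 gene, was in the upper component in 98 samples and the lower in 39, and the transcription factor gene MAF was in the upper component in 53 and the lower in 84. The kappa light chain gene IGKC split into 78 and 59 samples. The cyclin genes CCND2 and CCND3, the integrin gene ITGB7, the chemokine receptor genes CX3CR1 and CCR1, MYC and IRF4 did not meet the mixture rule. CX3CR1 missed it only because its upper component held 5 samples. CCND3, with 6 samples in its upper component, missed it only because its BIC was lower by 8.6. Of the 5880 genes, 859 did, and the smaller component was the higher one for 226 and the lower one for 633. With the floor at the 25th percentile these numbers were 428 and 498, so the balance between them depended on the floor.

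The most variable gene was UCHL1, which encodes a ubiquitin hydrolase, with a mean log2 signal of 9.20 ± 3.17 (SD over all samples). AZGP1, a secreted glycoprotein gene, had an SD of 2.95, the lambda light chain gene IGLC1 2.87, the interferon-induced gene IFI27 2.82 and FAM30A, a noncoding RNA gene, 2.79. The signaling regulator gene RGS13, the endothelin receptor gene EDNRB, the protease inhibitor gene TIMP1, FGFR3 and FRZB followed, with SDs from 2.64 to 2.70. The rest of the 20 were CD9, CD27, PPBP, KCNS3, LCP1, G0S2, RSAD2, TSPAN7, RNASE6 and SMAD1, with SDs from 2.34 to 2.55. Over all 5880 genes, 60 had an SD above 2, and the median SD was 0.62. The count of 60 depended on the floor, since it was 31 with the floor at the 25th percentile and 34 with a pseudocount.

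Genes of 1 list often moved together across the samples. The ribosomal protein genes had a median pairwise r of 0.639 over 32 members, and the proliferation genes had 0.50 over 37. After quantile normalization these were 0.175 and 0.499, so the first value depended on the scaling of the arrays. The markers of megakaryocytes, granulocytes and monocytes had 0.487, 0.424 and 0.382, although the selection was for plasma cells. The interferon-stimulated genes had 0.343, MHC class II genes 0.308, the immediate early response 0.264, cancer-testis antigens 0.259 and the unfolded protein response 0.233. Oxidative phosphorylation had 0.195, the proteasome 0.183, erythroid markers 0.173, T and NK cell markers 0.167 and immunoglobulin genes 0.133. Osteoblast and stromal markers had 0.105 and NF-kB targets 0.103. These 17 of the 24 lists lay above the 95th percentile of random lists of matched size and level, and from 17 to 19 did under the alternatives. Osteoblast and stromal markers did not in the lower title numbers, and plasma cell markers did after quantile normalization, with the mean of all probe sets and in the lower title numbers. Glycolysis and hypoxia did with a pseudocount, with the mean of all probe sets and in the higher title numbers. B cell markers and the translocation and cyclin D genes did in the lower title numbers, and Wnt ligands with receptors and pathway genes in the higher. Without these changes 7 lists did not, with plasma cell markers at 0.0563, B cell markers at 0.0445, Wnt antagonists at 0.0342, glycolysis and hypoxia at 0.0251, osteoclast-activating factors at 0.0250, Wnt ligands with receptors and pathway genes at 0.0102 and the translocation and cyclin D genes at -0.002.

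Several ribosomal protein genes were low on a few arrays. RPS9 and RPLP1 each lay over 2 log2 units below their median in 10 samples, RPS14 and RPS18 in 9, RPL8 in 8 and RPS19 in 6. Of the 32 ribosomal protein genes, 10 lay that low on at least 1 array and 6 on at least 5. On 11 arrays at least 3 of the genes were low at once, and 10 of the 11 were among the 69 with higher title numbers. This count was chosen after the values were seen.

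**Figure D2:**
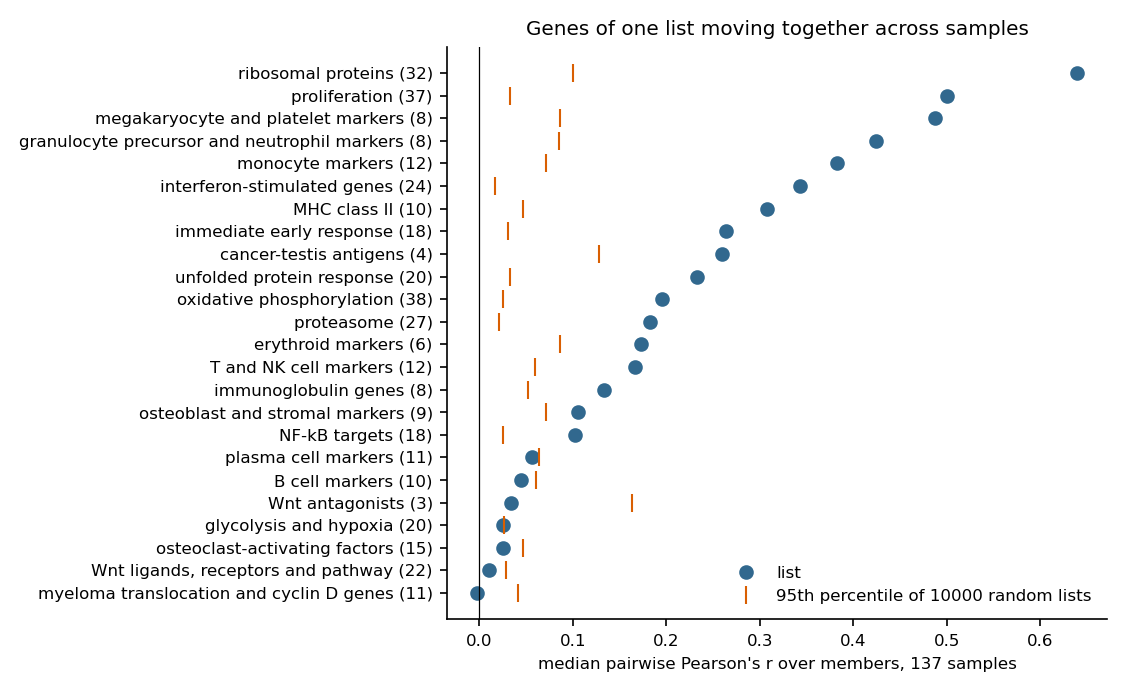
Median pairwise Pearson's r over the members of each of 24 gene lists (horizontal axis, dots) across all samples, with the 95th percentile of 10000 random lists of matched size and level (bars). Without quantile normalization the ribosomal protein list had the highest value, 0.639, and the translocation and cyclin D list the lowest, -0.002.

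The scores of the myeloid lists rose and fell together. Monocyte and granulocyte markers had r 0.766 (permutation p 1e-05, the smallest it can give) and rho 0.744 (p 1e-05) over all samples. That r was 0.744 without the 2 farthest samples, 0.763 in the lower title numbers and 0.762 in the higher. Granulocyte and megakaryocyte markers had r 0.716 and rho 0.713 (p 1e-05 each), with 0.698 without the 2 farthest samples and 0.689 and 0.732 in the title-number subsets. B cell markers ran against the proteasome genes, which encode the protein-degrading complex, with r -0.446 and rho -0.397 (p 1e-05 each). That relation had r -0.460 without the 2 farthest samples and -0.545 and -0.350 in the lower and higher title numbers. Each of these relations had an adjusted p of 5e-05. The B cell markers themselves moved together little, with a median pairwise r of 0.0445, and 0.0102 after quantile normalization. In all, 253 pairs of lists whose scores had no clusters were tested, and 83 passed an adjusted p of 0.05 with a positive r and 36 with a negative r. After quantile normalization 66 of 210 pairs passed. Of the 98 earlier pairs that were tested again, 61 still passed and 1 changed sign.

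DKK1 rose with FRZB, its fellow Wnt antagonist, which had the largest positive slope among the named genes at 0.39 ± 0.09 (SE, all samples, limma adjusted p 0.00876). ITGA8, an integrin subunit gene, had a slope of 0.31 ± 0.06 (adjusted p 0.00134), and HOMER1, a synaptic scaffold gene, had 0.24 ± 0.04 (adjusted p 4.08e-05). MOXD1, a monooxygenase gene, had 0.25 ± 0.05 (adjusted p 0.000279). Of the genes that fell as DKK1 rose, ABLIM1, which encodes an actin-binding protein, had the largest slope at -0.23 ± 0.07 (adjusted p 0.0321). The fractalkine receptor gene CX3CR1 had -0.21 ± 0.06 (adjusted p 0.0338), and the calcium-binding protein gene S100A10 had -0.18 ± 0.05 (adjusted p 0.0188). CX3CR1 was far higher in 5 samples than in the rest, and their weight in its slope was not tested. The other named positive genes were RSAD2, AJAP1, DCLK1, DUSP4, ETFB, CD1D, SYT1 and TNFSF10, with slopes from 0.22 to 0.31. The other named negative genes were AHNAK, CTSH, DPYSL2, MFGE8, ITGB1, CNKSR1, ST14, MYO1E and S100A11, with slopes from -0.20 to -0.13.

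Of 5879 genes tested against DKK1, 142 passed an adjusted p of 0.05, 41 with a negative slope and the rest, 71.1 percent, with a positive slope. Without the arrays of low ribosomal protein signals, left out after seeing the data, 77 were positive and 20 negative. Fits in the title-number subsets called fewer genes, 6 in the lower and 55 in the higher, while a fit with the subset as a block called 185. The median slope of the 142 genes was 0.961 times the pooled one in the lower and 1.05 times in the higher. The median SEs were 1.484 and 1.341 times as large. These genes were called with both subsets pooled, so part of that likeness was built in. Within the upper component of DKK1 limma called 4 genes. Within the lower component it called 0, with 311 at an unadjusted p under 0.05. The pooled fit had 999 at that p, which unrelated genes reach at a rate of 0.05. The median slope of the 142 genes was 1.044 times the pooled one in the upper component, where the median SE was 1.855 times as large and 0.7 percent of the genes changed sign. In the lower component these were 0.695 times, 5.262 times and 33.8 percent. CD1D had a slope of -0.018 ± 0.09 within the upper component, so its pooled slope did not hold there.

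FRZB rose with DKK1 at a slope of 0.30 ± 0.07 (SE, all samples, limma adjusted p 0.00223) and with ADM, the gene of the vessel-dilating peptide adrenomedullin, at 0.27 ± 0.06 (adjusted p 0.000773). TNFSF10, which encodes the death ligand TRAIL, had 0.22 ± 0.05 (adjusted p 0.000773). CD52, a lymphocyte surface gene, fell as FRZB rose, with a slope of -0.33 ± 0.07 (adjusted p 0.000274), and CD99, an adhesion gene, had -0.33 ± 0.06 (adjusted p 0.000209). The cyclin D2 gene CCND2 had -0.25 ± 0.05 (adjusted p 0.000603), and BAMBI, a decoy receptor gene of the TGF-beta pathway, had -0.22 ± 0.04 (adjusted p 1.67e-05). The other named positive genes were EDNRB, GNG11, TRIM22, RSAD2 and P2RY6, and the other named negative genes were AZGP1, CD81 and MFGE8.

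Of 5879 genes tested against FRZB, 563 passed, 313 with a positive slope and 250 with a negative slope. Without the arrays of low ribosomal protein signals these were 204 and 188. The title-number subsets gave 521 in the lower and 8 in the higher, and the block gave 614. The median slope of the 563 genes was 1.195 times the pooled one in the lower title numbers and 0.813 times in the higher. The median SEs were 1.356 and 1.45 times as large, and 0.2 and 0.5 percent of the genes changed sign. These genes were called with both subsets pooled, so part of that likeness was built in. The difference between the subsets was not tested. Within the upper component of FRZB limma called 0 genes, with 371 at an unadjusted p under 0.05, and within the lower component it called 1. The pooled fit had 1420 at that p, which unrelated genes reach at a rate of 0.05. The median slope of the 563 genes was 0.868 times the pooled one in the upper component, with a median SE 2.454 times as large and 5.7 percent of the genes changing sign, and ADM had a slope of -0.036 ± 0.12 there. In the lower component these were 0.939 times, 4.007 times and 17.9 percent.

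**Figure D3:**
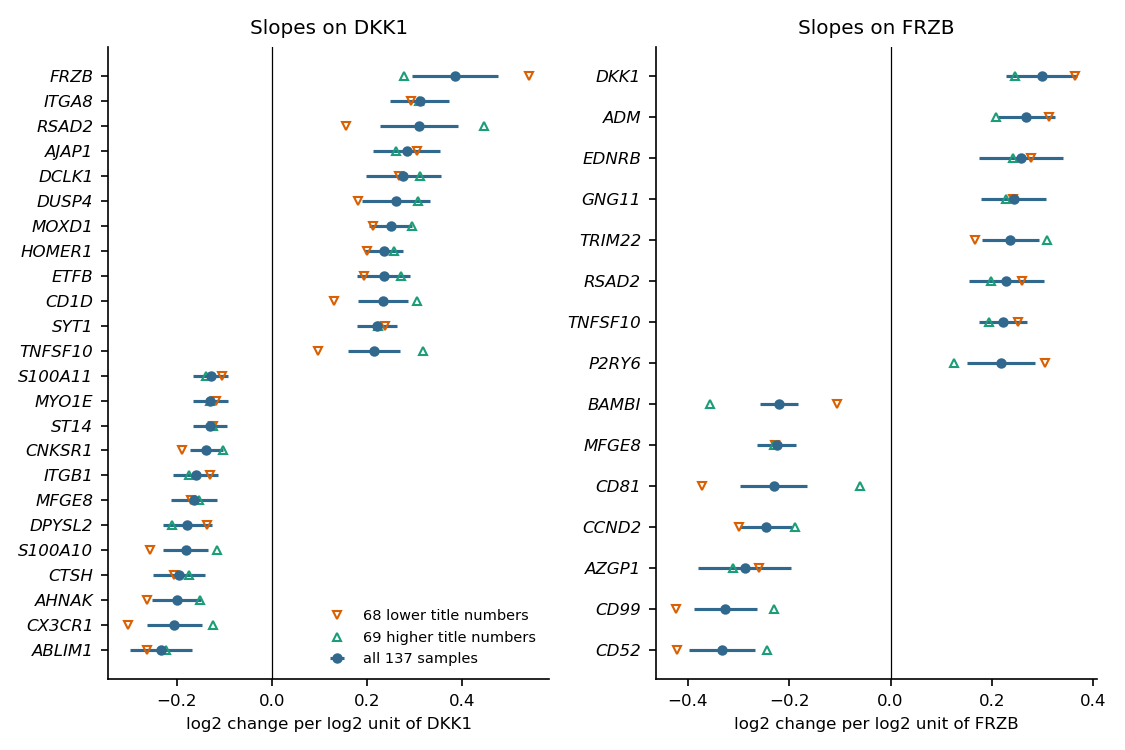
Slopes of the named genes reported here on DKK1 and FRZB (horizontal axis, log2 change per log2 unit) in all samples with their SE (dots and bars) and in the 68 samples with lower and the 69 with higher title numbers (triangles). All slopes shown kept their sign in both title-number subsets, as the naming rule required.

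The genes of DKK1 and FRZB overlapped. Of the 100 positive DKK1 genes that were also tested against FRZB, 51 were positive for FRZB. Of the 41 negative genes, 22 were negative for FRZB, and 0 genes called for both went opposite ways, with limma as the test of both. Some overlap follows from the relation between DKK1 and FRZB themselves, and its excess was not tested. RSAD2, an antiviral gene that interferon induces, and TNFSF10 were among the named genes of both, as was MFGE8, a gene of apoptotic cell clearance. A fit with the other antagonist as a covariate, chosen after seeing the data, called 28 genes for DKK1 and 306 for FRZB.

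Among 30 single genes of the bone lists tested against DKK1, FRZB was the 1 that passed (permutation p 8e-05, adjusted p 0.0024). Within the 87 samples in the upper components of both genes r was 0.319 (p 0.00257) and rho 0.325 (p 0.00214), with r 0.364 without the 2 farthest samples and an adjusted p of 0.0103 over 4 strata. In the 21 samples with DKK1 upper and FRZB lower r was 0.388 (p 0.0832) and rho 0.386 (p 0.0849). In the 15 samples with DKK1 lower and FRZB upper r was 0.0635 (p 0.819) and rho 0.154 (p 0.581), and in the 14 lower for both r was 0.255 (p 0.376) and rho 0.327 (p 0.252). Over all samples in the upper component of FRZB, whatever the level of DKK1, the relation had p 0.337 (p 0.055 for rho), and DKK1 had a slope of 0.171 ± 0.175 on FRZB. Within the lower component of FRZB it had p 0.00414 (p 0.00236 for rho). The test of FRZB passed in the lower title numbers (p 0.00013, adjusted p 0.0039) and failed in the higher (p 0.0305, adjusted p 0.916). None of the osteoclast-activating factors tested passed. Of the 24 measured, 15 met the filter on low genes, and several of the rest were at the floor in most samples. The macrophage chemokine gene CCL3 had p 0.587, IL6 had p 0.854, the hepatocyte growth factor gene HGF had p 0.642, TNF had p 0.465 and VEGFA had p 0.0947. The smallest p among them was that of ANXA2, an annexin gene, at 0.0386 with an adjusted p of 0.578.

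Genes of oxidative phosphorylation, which encode the mitochondrial respiratory chain, tended to rise with DKK1. COX7C had a slope of 0.063 ± 0.015 (SE, all samples, limma adjusted p 0.00978), and NDUFB1, NDUFB5 and UQCRB passed as well. Those were 4 of the 38 members tested, and 12 passed when adjusted over the list alone, all with positive slopes. The list's score passed with DKK1 (permutation p 0.0039, adjusted p 0.0468 over 24 lists), as did the score of the Wnt antagonists, which held FRZB and DKK4 alone (p 0.00348, adjusted p 0.0468). No other list passed. The oxidative phosphorylation score failed after quantile normalization (adjusted p 0.0818), with no filter (0.0775), with the mean of all probe sets (0.0508) and with the title block (0.0678), among 9 of 15 alternatives chosen before. Within the upper component the oxidative phosphorylation score had r 0.172 (p 0.0732) and rho 0.137 (p 0.156), with 0.160 without the 2 farthest samples. Within the lower component it had r -0.094 (p 0.623) and rho -0.150 (p 0.435). Neither list passed in either title-number subset, with adjusted p from 0.0811 to 0.862.

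Single members of other lists also rose with DKK1. The B cell receptor gene CD79A had a slope of 0.20 ± 0.05 (limma adjusted p 0.0213), JCHAIN had 0.12 ± 0.03 (adjusted p 0.015) and the ribosomal gene RPL35 had 0.056 ± 0.016 (adjusted p 0.0365). Adjusted over the list alone these 3 still passed, and so did the globin gene HBD and the unfolded protein response genes DNAJB9 and SEC61B. In the translocation and cyclin D list CX3CR1 passed over all genes, and CX3CR1 and CCND2, both negative, passed when adjusted over the list alone. In the remaining lists no member passed with limma over all genes or over the list alone.

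Most of the translocation and cyclin D genes had negative slopes on FRZB, and 3 of the 11 had slopes above 0. CCND2, NSD2 and CX3CR1 had negative slopes, -0.18 ± 0.04 for NSD2 (SE, all samples, limma adjusted p 0.000756) and -0.20 ± 0.05 for CX3CR1 (adjusted p 0.00456), while CCND1 had a positive slope of 0.21 ± 0.07 (adjusted p 0.0399). The weight of the 5 samples high for CX3CR1 in its slope was not tested. NSD2, high in 16 samples, and CCND1 fell into clusters themselves, so their slopes may rest on the difference between clusters. Adjusted over the list alone, CCND1 was positive and 7 of the 11 members were negative, with FGFR3, ITGB7, CCND3 and MAF added. The list's score passed (permutation p 1e-05, the smallest it can give, adjusted p 0.00024), and its samples fell into clusters. Within the upper component of FRZB r was -0.0786 (p 0.434, adjusted p 0.855) and rho 0.041 (p 0.681), and within the lower r was -0.335 (p 0.0489, adjusted p 0.293) and rho -0.316 (p 0.0647). It passed in the lower title numbers (adjusted p 0.00168) and failed in the higher (p 0.0256, adjusted p 0.197).

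Some interferon-stimulated genes, which cells switch on against viruses, rose with FRZB. MX1 had a slope of 0.16 ± 0.04 (limma adjusted p 0.00941), MX2 0.11 ± 0.03 (adjusted p 0.00746), IFI44 0.14 ± 0.04 (adjusted p 0.0171) and ISG20 0.069 ± 0.023 (adjusted p 0.0356). Of 24 members 5 passed over all genes and 13 when adjusted over the list alone, all positive. Their score passed (permutation p 0.00247, adjusted p 0.0198), as did the Wnt antagonists (p 0.0023, adjusted p 0.0198), and 3 of the 24 lists passed in all. With FRZB left out the Wnt antagonists held DKK1 and DKK4 alone, so that pass repeats in part the relation of FRZB with DKK1. The interferon score failed without the 2 extreme samples (adjusted p 0.0509), without low-correlation arrays (0.108) and with the translocation and cyclin D covariates (0.243). Within the upper component of FRZB the interferon score had r 0.0875 (p 0.382) and rho 0.120 (p 0.229), and within the lower r -0.050 (p 0.778) and rho -0.035 (p 0.843). In the title-number subsets it had adjusted p of 0.132 and 0.197.

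Members of other lists moved with FRZB in both directions. The stress sensor gene ATF6 fell with a slope of -0.096 ± 0.017 (limma adjusted p 7e-05), and the translocon gene SEC61B rose at 0.048 ± 0.011 (adjusted p 0.00229). The cell cycle genes CDC20, MCM5 and CKS1B fell and CKS2 rose, as 4 of 37 proliferation genes, over all genes and when adjusted over the list alone. The ribosomal genes RPL22, RPS15, RPL35 and RPL37 rose among 7 of 32, and 7 passed when adjusted over the list alone. Oxidative phosphorylation genes rose for 4 members and fell for 1, NDUFS1, and adjusted over the list alone for 6 and 1. The kinase gene CSNK1A1, the MHC class II chaperone gene CD74 and ADM rose and the interleukin receptor gene IL6R fell, each past the threshold both ways. Adjusted over the list alone, the plasma cell gene POU2AF1 and the unfolded protein response gene DNAJB9 were positive as well. The proteasome genes PSMA4 and PSMB7 rose, and PSMB7 passed when adjusted over the list alone.

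No list of markers of other marrow cells passed with either antagonist, which does not show that they stayed level. The smallest adjusted p among the 7 lists of other cell types was 0.196, for erythroid markers with FRZB. Monocyte markers had p 0.507 with DKK1 and p 0.116 with FRZB, and granulocyte markers had p 0.733 and 0.971. On FRZB, 1 of 12 monocyte and 0 of 6 erythroid markers had a slope above 0, with median slopes of -0.0661 and -0.0328, and on DKK1 1 of 12 T and NK cell markers did, with a median of -0.0173. With the scores of these 7 lists as covariates limma called 143 genes for DKK1 and 495 for FRZB.

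The genes that moved with FRZB were unevenly spread over the chromosomes of assembly GRCh38.p14. Chromosome 9 held 43 positive genes, 20.57 percent of its 209 genes, and 1 negative gene. The next highest positive shares were 12.11 percent on chromosome 11, 10.99 on 13, 10.38 on 3, 10.3 on 15 and 9.88 on 5. Chromosome 1 held 70 negative genes, 11.86 percent of its 590, and chromosome 8 held 20, 10.15 percent of its 197. For DKK1 the highest positive shares were 6.72 percent on chromosome 5, 5.26 on 9, 4.4 on 13 and 4.08 on 14, and the highest negative shares were 2.06 percent on chromosome 22 and 1.89 on 10.

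**Figure D4:**
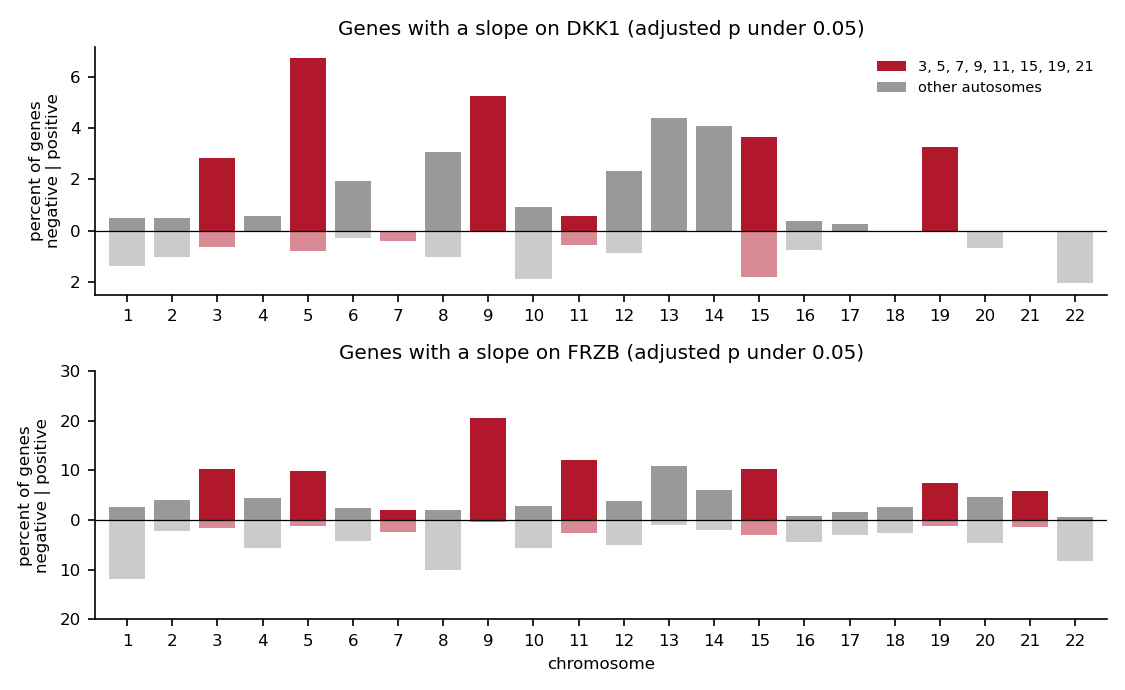
Percent of the genes of each autosome (horizontal axis) with a positive slope (above 0) or a negative slope (below 0) on DKK1 and on FRZB at a limma adjusted p under 0.05. Chromosomes 3, 5, 7, 9, 11, 15, 19 and 21 are in red, and chromosome 9 had the highest positive share for FRZB, 20.57 percent.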

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

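Tests within or blocked by the mixture components, without arrays of low ribosomal signals, and with the odd-numbered chromosome score or the other Wnt antagonist as a covariate were chosen after seeing the data, as were all alternatives of the odd-numbered chromosome score and the fit without the 2 extreme samples for single bone genes. The others were chosen before. The count of genes related to DKK1 stayed within 1.5 times 142, from 97 to 185, and that for FRZB within 1.5 times 563, from 392 to 614, under every setting not given below.

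The genes called made up 2.42 percent of those tested for DKK1 and 9.58 percent for FRZB. With the translocation and cyclin D genes as covariates, which were 6 genes, these shares were 0.46 percent (27 genes) and 0.119 percent (7 genes). The lower title numbers gave 0.102 percent (6 genes) for DKK1, and the higher gave 0.936 percent (55 genes) for DKK1 and 0.136 percent (8 genes) for FRZB. Within the upper component DKK1 gave 0.068 percent (4 genes) and FRZB 0, within the lower 0 and 0.017 percent (1 gene), and with the component as a block 0.017 percent (1 gene) each. The odd-numbered chromosome score left 0.987 and 2.16 percent, and the other Wnt antagonist as a covariate left 0.476 percent (28 genes) and 5.21 percent (306 genes). Beside the counts of 0, limma had 371 genes at an unadjusted p under 0.05 for FRZB within the upper component and 311 for DKK1 within the lower. The pooled fits had 1420 and 999 at that p, which unrelated genes reach at a rate of 0.05. A Spearman test per gene gave 140 and 509. The components were cut from the level of DKK1 or FRZB itself. Fits within or blocked by them therefore have less of its spread and larger SEs. The cause of the other changes was not tested. Sample number does not explain the difference between the title-number subsets, which held 68 and 69 samples.

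For the named genes on DKK1, 272 slopes under the alternatives chosen before kept their direction and call and 78 kept the direction alone. On FRZB these were 181 and 48. Under those chosen after, 27 did so for DKK1 and 30 for FRZB, 8 and 2 reversed, and the rest kept the direction alone. Within the lower component of DKK1 the reversed slopes were FRZB -0.344, ITGA8 -0.101, RSAD2 -0.440, TNFSF10 -0.104, CTSH 0.385, S100A10 0.179 and MYO1E 0.164, and CD1D reversed in the upper at -0.018. On FRZB, ADM had -0.036 in the upper component and CD81 had 0.262 in the lower. Adjusted p of these ran from 0.906 to 0.982. The covariate CCND2 has no slope in the fit that holds it, and genes dropped by the stricter filter have none there. The naming rule fixed the direction in both title-number subsets in advance, so the kept directions there are no test. The totals for FRZB include the gene that is not reported here.

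Of 2 lists related to DKK1, 0 remained past the permutation threshold after quantile normalization, with no filter, with the mean of all probe sets, with the translocation and cyclin D genes as covariates, without low-correlation arrays, in the lower or higher title numbers, with the title block, in the upper or lower component and with the component block. The count was 1 without the 2 extreme samples, with the proliferation score and without arrays of low ribosomal signals. Of 3 lists related to FRZB, 0 passed with the translocation and cyclin D covariates, where the list of those genes was not tested, and 0 in the higher title numbers, in the upper or lower component and with the component block, and 1 passed without the 2 extreme samples and without low-correlation arrays. Within the lower components r was -0.094 for oxidative phosphorylation with DKK1 and -0.050 for interferon-stimulated genes with FRZB. The cause was not tested.

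Of the single bone genes, 0 passed in the higher title numbers and in the lower component, where FRZB had r -0.112 with DKK1 over both components of FRZB. In the upper component 2 passed, FRZB and SFRP1, which fell as DKK1 rose (permutation p 0.00125, p 0.00277 for rho, adjusted p 0.0188). SFRP1 fell into clusters, so no r is given, and it was at the floor in 46.7 percent of samples. In the lower component the odd-numbered chromosome score had p 0.857 with DKK1 with a reversed sign. Pairs of lists numbered 66 after quantile normalization and 75 in the lower title numbers. Genes with separate clusters numbered 176 with means over 4 SD apart, 313 in the lower and 293 in the higher title numbers, where fewer samples were fitted. Of the 20 most variable genes, from 15 to 20 remained among the top 20 under the alternatives. Signal near the floor limits what can be said of WIF1, TNFRSF11B, MMP13, IL11 and TNFSF11. They were at the floor in 89.8, 87.6, 86.1, 78.8 and 54.7 percent of samples.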

Other observations

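Tests within components and strata, tests of single chromosomes, fits with the odd-numbered chromosome score or the other Wnt antagonist as a covariate, and the count of samples high for both FGFR3 and NSD2 were chosen after the results were seen, and the other tests below were chosen before. FGFR3 was in the upper component in 13 samples and NSD2 in 16, and 11 samples were in both, where 1.52 would be if the genes were independent (Fisher's exact test, p 5.97e-11). Both genes lie at the breakpoint on chromosome 4 of the translocation between chromosomes 4 and 14.

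The 142 genes that moved with DKK1 exceeded chance: 1 of 100 pairings of the level with the samples, the real one, gave as many, and the highest of the others gave 3. RNA quality, array scaling and a shift in level by title number are argued against as the whole source. Other cell types are argued against only as far as the scores of their marker lists measure them. The B cell markers had a median pairwise r of 0.0445, below the 95th percentile of random lists, so their score may measure those cells poorly. No covariate stood for normal plasma cells. With RNA quality, other cell types or title number in the fit 98.6, 83.7 and 97.2 percent of the genes kept their sign and call, and after quantile normalization 90.1 percent. The title-number block cannot speak to relations that differ between the subsets. Within the lower and higher title numbers alone 3.5 and 26.8 percent were kept, with fewer samples in each fit. Tumour subtype stays open and cannot be told apart from other sources, since 18.3 percent were kept with the translocation and cyclin D genes as covariates, between the bounds of 10 and 50 percent set beforehand. In that fit the median slope was 0.837 times and the median SE 1.002 times that without them, so smaller slopes and not a larger spread ended most calls. With the component as a block the median slope was 0.948 times and the median SE 1.787 times as large. The component was cut from the level of DKK1 itself, so the block shares the spread of DKK1, and a larger SE follows. No biological explanation named by the design was tested, since the design gives 1 group.

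The 563 genes that moved with FRZB also exceeded chance, with 1 of 100 pairings as large and a highest other count of 2. With RNA quality, other cell types or title number in the fit 88.5, 74.8 and 96.8 percent of the genes kept their sign and call, and after quantile normalization 88.9 percent. This argues against RNA quality, array scaling and a shift in level by title number as the whole source. It argues against other cell types only as far as their marker scores measure them, with the limits given for DKK1. The title-number block cannot speak to relations that differ between the subsets. Within the lower and higher title numbers alone 60.2 and 1.4 percent were kept, with fewer samples in each fit. With the translocation and cyclin D genes as covariates 1.2 percent were kept, and the median slope was 0.671 times and the median SE 1.108 times that without them. The genes that move with FRZB may therefore follow tumour subtype, a hypothesis that these arrays alone do not settle because subtype was read from the same arrays. With the component as a block the median slope was 0.886 times and the median SE 2.092 times as large. The larger SE thus took more from the calls than the smaller slopes. The component was cut from the level of FRZB itself, so the block shares the spread of FRZB, and a larger SE follows. No biological explanation named by the design was tested.

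Gains of the odd-numbered chromosomes 3, 5, 7, 9, 11, 15, 19 and 21, which many myelomas carry, could link the genes that move with DKK1 and FRZB: the score of their 2018 genes minus that of 3631 genes on other autosomes rose with DKK1 (permutation p 0.00295) and with FRZB (p 1e-05, the smallest it can give). Of those 2018 genes 9.91 percent were positive and 1.73 percent negative for FRZB, against 3.06 and 5.7 percent of the others, and for DKK1 58 were positive and 10 negative, against 43 and 29. The score fell into clusters of 69 and 68 samples, so no pooled r is given, and within the upper components p was 0.0076 for DKK1 and 0.0243 for FRZB, within the lower 0.857 and 0.405, and in the lower and higher title numbers 0.0183 and 0.117 for DKK1 and 1e-05 and 0.017 for FRZB, the last with a rho p of 0.173. With the score as a covariate 30.3 percent of the DKK1 genes and 17.2 percent of the FRZB genes were kept, with median slopes of 0.877 and 0.705 times and median SEs of 1.022 and 1.076 times those without it. The score was built from all kept autosomal genes, the called ones among them. Its relation with each level, the shares of called genes and this loss of calls are therefore not separate evidence. Exceptions included chromosome 7 with 5 positive and 6 negative genes for FRZB and, for DKK1, chromosomes 7, 11 and 21 with 0, 2 and 0 positive genes. Outside the set chromosomes 13, 14 and 2 held 10, 12 and 16 positive and 1, 4 and 9 negative genes for FRZB. For DKK1 chromosomes 13 and 14 held 4 and 8 positive and 0 negative genes, and chromosomes 6, 8 and 12 also held positive genes. Chromosome counts were not used here. Within the upper component of the score r was 0.173 (permutation p 0.175, rho 0.159) for FRZB upper (n = 63) and -0.18 (p 0.173, rho -0.113) for DKK1 upper (n = 59). Within its lower component r was -0.215 (p 0.189, rho -0.198, n = 39) for FRZB upper and 0.145 (p 0.32, rho 0.105, n = 49) for DKK1 upper. The relation may therefore rest on the difference between clusters.

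Single chromosomes were then tested over 22 scores, of which the 3 with the smallest adjusted p are given for each gene. For FRZB, chromosome 9 rose (permutation p 1e-05, adjusted p 0.00022), and chromosomes 1 and 8 fell (adjusted p 0.00055 and 0.00081). The lowest adjusted p of the 22 for FRZB was 0.211 within the upper component, 0.784 within the lower and 0.152 in the higher title numbers, so these relations were not called there, and chromosome 8 had r 0.204 in the lower component. For DKK1, chromosome 22 fell (adjusted p 0.00792) and chromosomes 5 and 9 rose (adjusted p 0.0103 each). The lowest adjusted p of these 3 was 0.115 within the upper component, 0.854 within the lower, and 0.0749 and 0.0862 in the lower and higher title numbers, so these relations were not called there either. Chromosome 14, whose score fell into clusters, also rose with DKK1 (adjusted p 0.0175) and was called in the higher title numbers (adjusted p 0.0431) but not in the lower (0.705), nor within the upper component (0.467) or the lower (0.945). In the lower component chromosome 22 had r 0.165 and chromosome 5 had r -0.22, with reversed signs.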
